A study of Homo sapiens with 12 samples.

How the data were processed

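Total RNA and polysomal RNA of the human neuroblastoma cell line CHP134 were measured on 12 single-colour Agilent arrays. Polysomal RNA is the RNA recovered from the heavy, ribosome-laden part of a sucrose gradient, and its composition is read here as a guide to what the cells were translating. Noncoding RNAs were measured in it too, so it may not be translated RNA alone. Cells received either vehicle or the iron chelator CPX at 5 µM for 24 h, which with both RNA kinds made 4 groups of 3 arrays: vehicle total, CPX total, vehicle polysomal and CPX polysomal. Per the series' design text each replicate was a separate experiment begun from seeding of cells. Sample titles call the control cells untreated, whereas the treatment protocol states vehicle, and the latter wording is used here. Per the labels' protocols, total RNA came from a column kit, and polysomal RNA from cycloheximide-treated lysates by gradient, proteinase K and phenol-chloroform. Contrasts of polysomal against total RNA therefore include the extraction, and total RNA also includes nuclear RNA.

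Per the file headers, the deposited scanner files hold spot intensity values from Agilent Feature Extraction 10.7.3.1, where the submitters' processing notes give version 10.7.7.1. The processed intensity had been background-subtracted and spatially detrended on each array and was not normalized between arrays. The files also hold raw spot and local background intensity. The authors' own value table is on a log2 scale, and its equal array medians and matching distributions show quantile normalization. It was used only as an alternative. The file headers name array design 014850 and genome build hg19, and all probe coordinates given are those of the files in that build.

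Each array carried 45015 spots, of which 43376 were not controls, for 41000 distinct probes. Through their accession 27294 probes took a current RefSeq gene symbol, 2383 already carried a current symbol, 229 were named through a synonym that belongs to 1 gene, and 11094 kept the name in the file. Control spots and spots with an outlier mark were left out, and 53 probes had no other spot. No non-control spot was saturated. The processed intensity was divided by the 75th percentile of the array's non-control probes and taken to log2. Probes well above background on all 3 arrays of at least 1 group were kept, 30441 in all, and 10506 dim probes were left out. Each gene was represented by its kept probe with the highest mean, which gave 21714 genes, 6377 of them with more than 1 kept probe. The number of arrays limits the precision of every value. From 70.86% to 77.87% of probes were well above background per array.

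A single model with 4 group means was fitted to all 12 arrays (limma 3.58.1, lmFit and eBayes, in R 4.3.3 with the data.table package, version 1.17.8), and a gene was called when its Benjamini-Hochberg adjusted p was under 0.05. There were 5 contrasts: CPX against vehicle in total RNA, the same in polysomal RNA, the difference between these responses (an interaction, here the change of polysomal loading), and polysomal against total RNA in vehicle cells and in CPX cells. All tests were two-sided. An error after ± is a standard error of the log2 fold change from the fit unless it is named an SD, with n = 3 arrays in each group. Genes not well above background on any array of a group have a lower bound of the fold. It sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal well above background.

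A set of 44 gene lists was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated from the residuals and with limma's rotation test fry. With the estimated correlation only the hypoxia list in total and in polysomal RNA and the mitosis list in total RNA held. The lists overlap and are not independent. Among HIF list members, P4HA1, P4HA2, KDM3A, JMJD6, SLC2A1, DDIT4 and STC2 also stand in other lists. The groups, contrasts, 44 gene lists, alternatives and the rule for naming genes were fixed before the data were examined, while some tests of explanations were chosen later, as the closing section says. The rule allowed, per contrast, the 8 largest rises and 8 largest falls among called genes whose replicates did not overlap between the groups (for the interaction, called genes only), measured well above background in all groups compared; up to 5 genes per direction measured in 1 group only; up to 3 called members per direction of each list; and 45 genes named in advance. The text prints a part of the genes so allowed, picked after their values and the results of leaving out arrays were seen and with preference for calls that held, so the printed genes are steadier than the whole set. The test was checked on simulated arrays drawn from the real means and spread of each gene, with known changes in 200 genes for the responses and in 200 others for the interaction. At a simulated log2 change of 1, 73.1% of changed genes were called in the total RNA contrast, 77.6% in the polysomal contrast and 26.9% in the interaction. False calls numbered 5, 10 and 4 of 21274 unchanged genes. A list shifted alike in both fractions had camera p of 4.85e-13 in total and 1.95e-16 in polysomal RNA, and 0.195 in the interaction, where it had no change to find. The simulated noise was independent between genes and between arrays, so this check says nothing on lists of correlated genes or on shared slides. The real responses called 42.1% of genes in total and 45.3% in polysomal RNA, far more than were changed here. The adjusted threshold was therefore stricter in the simulation, and its call rates do not carry over to these responses.

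The 3 slides carried 4 arrays each, 1 of every group, and the slide number equals the replicate number. Slide and replicate experiment thus cannot be told apart, while every contrast is balanced over slides, so that a slide term leaves each fold change as it was and alters only its error. Alternatives were normexp background correction, quantile normalization, scaling to the median, the authors' value table, no filter or a stricter filter on dim probes, the mean of a gene's probes, the slide or replicate as a block, only the arrays of a contrast, a trended robust variance, array weights, a threshold of 2-fold, and leaving out each array in turn. Scaling each array to its own signal removes any change in the amount of polysomes or of RNA per cell, so all values describe composition.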

Results

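The response of CHP134 neuroblastoma cells to iron chelation was measured in the transcriptome (total RNA) and in the translatome (polysomal RNA) after 24 h of 5 µM CPX. Each of the 4 groups held 3 arrays. The 75th percentile of the processed intensity ranged from 1467 to 2721 between arrays, and replicates of a group correlated with Pearson's r of 0.9888 to 0.9961 across genes. Genes within an array are not independent replicates.

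The comparison of CPX with vehicle in total RNA addressed the change of transcript levels. Targets of the hypoxia-inducible factor HIF rose throughout: of 39 measured list members 39 were called higher, with a median log2 change of 2.90 (camera adjusted p = 3.81e-29, and adjusted p = 0.00179 with an estimated correlation). ADM, encoding the vasodilator peptide adrenomedullin, rose by 8.93 ± 0.145 on the log2 scale (adjusted p = 7.8e-11), a 486-fold change and the largest called rise among genes measured in both groups. Cell division genes fell together: 41 of 43 members of the G2/M and mitosis list were lower, none was higher, and the median was −0.91 (adjusted p = 8.77e-22, and 0.0245 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell by 2.78 ± 0.124 (adjusted p = 6.78e-08). TFRC, the transferrin receptor that brings iron into cells, rose by 1.15 ± 0.109 (adjusted p = 1.58e-05).

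Among other HIF targets in total RNA, the carbonic anhydrase gene CA9 rose by 4.73 ± 0.444, the kinase gene PDK1 by 4.58 ± 0.174, NDRG1 by 4.38 ± 0.144 and the angiogenic factor gene VEGFA by 3.81 ± 0.14, all on the log2 scale with adjusted p of at most 1.46e-05. The transcription factor genes BHLHE40 and RORA rose by 6.53 ± 0.226 and 5.61 ± 0.398. Glycolysis genes were higher in 17 of 18 cases with a median of 1.32 (adjusted p = 8.57e-11; adjusted p = 0.169 with an estimated correlation), led by the aldolase gene ALDOC at 4.22 ± 0.122, the lactate transporter gene SLC16A3 at 3.73 ± 0.125 and the enolase gene ENO2 at 3.01 ± 0.152. Of 11 collagen prolyl and lysyl hydroxylases, 7 were higher and none lower (median 0.64, adjusted p = 0.000567; adjusted p = 0.116 with an estimated correlation), P4HA1 by 3.52 ± 0.202 and PLOD2 by 3.14 ± 0.125. Of 26 JmjC, TET and ALKBH dioxygenases, which like the HIF prolyl hydroxylases need iron, 13 were higher and 3 lower (median 0.25, adjusted p = 0.0109, and adjusted p = 0.308 with an estimated correlation). KDM3A rose by 2.28 ± 0.1 and KDM4C by 2.20 ± 0.145. Scaling to the array median moved every total RNA change by −0.23, about the size of this list median. Adjusted over the list alone, 39 HIF targets, 17 glycolysis genes, 8 collagen hydroxylases and 13 dioxygenases were higher. P4HA1 and KDM3A are also members of the HIF list.

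Among 30 p53 targets in total RNA, 24 were higher and 1 lower, with a median of 0.94 (adjusted p = 7.63e-12; adjusted p = 0.116 with an estimated correlation), and adjusted over the list alone the counts were 25 and 1. GDF15, a stress-induced cytokine gene, rose by 4.50 ± 0.225, the cyclin-dependent kinase inhibitor gene CDKN1A by 2.96 ± 0.133 and PHLDA3 by 2.68 ± 0.106. Immediate-early genes were higher in 17 of 23 cases and lower in none (median 1.14, adjusted p = 4.66e-08; adjusted p = 0.116 with an estimated correlation), or 18 adjusted over the list alone. DUSP5 rose by 3.59 ± 0.152 and NR4A3 by 3.46 ± 0.151, and EGR3, not well above background in vehicle total RNA, was at least 6.83-fold higher. The list of integrated stress response targets of ATF4 had 9 members higher and 12 lower (median −0.27, adjusted p = 0.465). Its members DDIT4 (also in the HIF list), ATF3 and TRIB3 rose by 2.91 ± 0.116, 2.79 ± 0.158 and 1.63 ± 0.151. In contrast DDIT3, encoding the pro-apoptotic factor CHOP, was at −0.33 ± 0.335 (adjusted p = 0.474). Metallothionein genes were higher in 8 of 11 cases (median 0.64, adjusted p = 0.000761; adjusted p = 0.41 with an estimated correlation), led by MT3 at 3.46 ± 0.165, and near-identical family members cannot be separated with certainty by these probes.

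Replication, protein-degradation and mitochondrial lists were lower in total RNA. DNA replication genes were lower in 28 of 43 cases and higher in 1 (median −0.40, adjusted p = 4.64e-07; adjusted p = 0.266 with an estimated correlation), among them the polymerase subunit gene POLE2 at −1.28 ± 0.133 and the helicase subunit gene MCM5 at −1.04 ± 0.107. Proteasome subunits were lower in 26 of 31 cases (median −0.72, adjusted p = 8.57e-11; adjusted p = 0.266 with an estimated correlation), with PSMC2 at −1.17 ± 0.137. Mitochondrial ribosomal proteins were lower in 47 of 74 cases and higher in 1 (median −0.41, adjusted p = 8.57e-11; adjusted p = 0.412 with an estimated correlation), with MRPL20 at −1.13 ± 0.113. Nuclear genes of oxidative phosphorylation were lower in 29 of 74 cases (median −0.25, adjusted p = 1.18e-05; adjusted p = 0.465 with an estimated correlation), with the iron-sulfur subunit gene SDHB at −1.22 ± 0.331. In an adjustment within each list, 29 replication genes, 26 proteasome genes, 47 mitochondrial ribosomal protein genes and 28 oxidative phosphorylation genes were lower. Replication-dependent histones went both ways, 15 higher and 25 lower of 50 (median −0.57, adjusted p = 0.0425; adjusted p = 0.714 with an estimated correlation), with H1-5 at −4.86 ± 0.262, H1-3 at −3.96 ± 0.286 and H2AC7 at 2.23 ± 0.232. Histone genes resemble each other closely and their single values are uncertain.

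Of the 19 genes of iron handling in total RNA, 3 were higher and 4 lower, and the list was not called (median −0.13, adjusted p = 0.659). The ferritin subunit genes FTH1 and FTL were at −0.30 ± 0.263 (adjusted p = 0.407) and −0.33 ± 0.296 (adjusted p = 0.416), and both families have many processed pseudogenes whose signal the probes were not shown to exclude. EIF5A, the translation factor activated by the hypusine modification, fell by 0.79 ± 0.137, and the genes of the hypusine enzymes DHPS and DOHH fell by 0.45 ± 0.0925 and 0.59 ± 0.15. DOHH is itself an iron-dependent hydroxylase. The neuropeptide gene NPY fell by 3.36 ± 0.168 (adjusted p = 1.5e-07). The oncogene MYCN was at 0.27 ± 0.144 (adjusted p = 0.161). The smooth muscle myosin gene MYH11 rose by 7.44 ± 0.303 and RGS4, a regulator of G-protein signalling, by 6.56 ± 0.172. Among genes measured above background in CPX total RNA only, LY6K was at least 68.7-fold and the ephrin receptor gene EPHA3 at least 33.4-fold higher. NEUROD4, a neurogenic transcription factor gene, was at least 4.67-fold lower.

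In all, 4764 genes were higher and 4382 lower of 21714 tested in total RNA (limma, adjusted p under 0.05), and 2137 and 746 of these changed at least 2-fold. Of the called genes, 99.7% had the same sign on each of the 3 slides. The slides are the replicates behind the calls, so here and in the other contrasts this agreement is largely built in. With the slide as a block 5156 were higher and 4600 lower. The lower count rose to 6827 with scaling to the array median, which placed the median of all genes 0.23 lower (a shift of −0.23), and the higher count fell to 2335 with normexp background correction. Markers of other cell types were not called as lists: epithelial markers had 3 of 8 higher (adjusted p = 0.138) and blood cell markers 2 of 7 (adjusted p = 0.444).

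**Figure D1:**
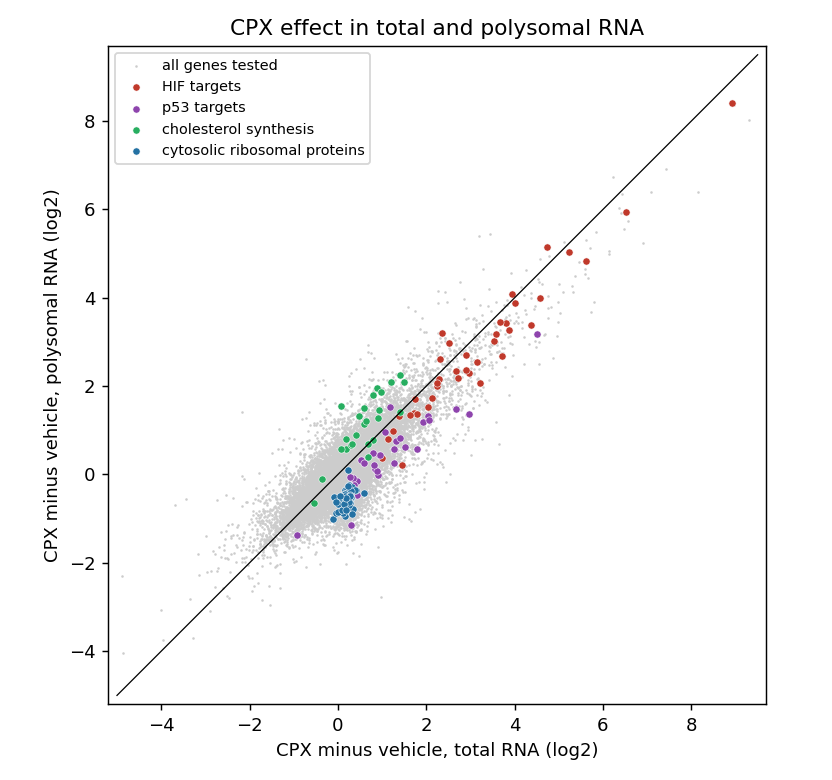
CPX-induced log2 fold change of each of 21714 genes in polysomal RNA (vertical axis) against total RNA (horizontal axis), with each gene a point. Members of the HIF target, p53 target, cholesterol synthesis and cytosolic ribosomal protein lists are in colour, and all other genes are grey. Most genes lie near the diagonal (Pearson's r = 0.827 across genes). The 116 genes called for higher loading lie above it and the 277 called for lower loading below, without a mark of their own.

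The comparison of CPX with vehicle in polysomal RNA addressed the change of the transcripts recovered with polysomes. HIF targets rose again, 38 of 39 with none lower and a median of 2.54 (adjusted p = 1.5e-29, and adjusted p = 0.0017 with an estimated correlation), and ADM rose by 8.40 ± 0.145. Cytosolic ribosomal protein genes fell: 63 of 81 were lower and none higher, with a median of −0.53 (adjusted p = 4.18e-11; adjusted p = 0.473 with an estimated correlation). Cholesterol synthesis genes rose, 22 of 25 higher and 1 lower, with a median of 1.21 (adjusted p = 1.05e-10; adjusted p = 0.23 with an estimated correlation). Mitotic genes were lower in 39 of 43 cases (median −0.74, adjusted p = 2.55e-13; adjusted p = 0.11 with an estimated correlation). DDIT3 rose by 2.15 ± 0.335 (adjusted p = 0.000501) in this fraction.

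Among ribosomal protein genes in polysomal RNA, RPL6 fell by 1.01 ± 0.121 and RPL28 by 0.94 ± 0.145, and 71 of the 81 were lower adjusted over the list alone. Their median was −0.87, −0.40 and −0.38 on the 3 slides. These genes have many pseudogenes, so a value for any 1 of them is uncertain. Translation initiation and elongation factors were lower in 30 of 48 cases and higher in 2 (median −0.44, adjusted p = 8.92e-05; adjusted p = 0.359 with an estimated correlation), with EIF3G at −0.97 ± 0.124 and the cap-binding protein gene EIF4E at −0.96 ± 0.134. Mitochondrial ribosomal proteins were lower in 66 of 74 cases (median −0.66, adjusted p = 5.89e-15; adjusted p = 0.298 with an estimated correlation) and oxidative phosphorylation genes in 57 of 74 (median −0.53, adjusted p = 1.32e-10; adjusted p = 0.319 with an estimated correlation), with none higher in either list. Proteasome genes were lower in 30 of 31 cases (median −0.81, adjusted p = 4.18e-11; adjusted p = 0.23 with an estimated correlation), with PSMA5 at −1.25 ± 0.11. Histones were lower in 32 of 50 cases and higher in 4 (median −1.03, adjusted p = 1.78e-06; adjusted p = 0.49 with an estimated correlation), with H1-5 at −4.03 ± 0.262 and H4C3 at −3.71 ± 0.288. Adjusted over the list alone, 33 translation factors, 66 mitochondrial ribosomal proteins, 61 oxidative phosphorylation genes, 31 proteasome genes and 34 histones were lower.

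Among cholesterol synthesis genes in polysomal RNA, the synthase gene HMGCS1 rose by 2.25 ± 0.203, the oxidase gene MSMO1 by 2.10 ± 0.2 and INSIG1, a regulator of the pathway, by 2.10 ± 0.209. In total RNA 17 of these 25 genes were higher and 2 lower (median 0.64, adjusted p = 0.00024; adjusted p = 0.412 with an estimated correlation), with HMGCS1 at 1.41 ± 0.203 as an example. Within the list, 23 were called higher in polysomal and 18 in total RNA. p53 targets were higher in 17 of 30 cases and lower in 2 in polysomal RNA (median 0.44, adjusted p = 6.59e-05; adjusted p = 0.277 with an estimated correlation), with GDF15 at 3.18 ± 0.225, PHLDA3 at 1.47 ± 0.106 and CDKN1A at 1.36 ± 0.133. The p53-induced glycolysis regulator gene TIGAR fell by 1.15 ± 0.145. Integrated stress response genes were higher in 12 of 36 cases and lower in 5 (median 0.25, adjusted p = 0.0151, and adjusted p = 0.505 with an estimated correlation). STC2, also a member of the HIF list, was at 4.09 ± 0.186. Adjusted over the list alone, the counts were 17 higher and 2 lower for p53 targets and 12 and 5 for the stress response.

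For iron handling in polysomal RNA, FTL fell by 1.46 ± 0.296 (adjusted p = 0.0024) and FTH1 by 1.29 ± 0.263 (adjusted p = 0.0025), and TFRC rose by 0.95 ± 0.109 (adjusted p = 7.35e-05). The list had 2 of 19 members higher and 6 lower (median −0.24, adjusted p = 0.631). Of the transcripts measured in only 1 group, the circadian repressor gene BHLHE41 was at least 305-fold and the secreted lipase inhibitor gene ANGPTL4 at least 234-fold higher. The Wnt inhibitor gene DKK1 fell by 2.64 ± 0.48 and NPY by 2.82 ± 0.168.

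In polysomal RNA 4440 genes were higher and 5399 lower, of which 1944 and 758 changed at least 2-fold. The same sign was found on all 3 slides for 99.8% of called genes, and with the slide as a block 4755 were higher and 6125 lower. With normexp background correction 2505 were higher.

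The responses of the fractions held largely the same genes. In both, 3393 genes were called higher and 3351 lower, against 974.1 and 1090 for independent lists, and 44 were called in opposite directions. Fold changes correlated with Pearson's r = 0.827 and Spearman's rho = 0.722 across genes, and with r of 0.706 to 0.761 within single slides. Of 2358 genes called in total RNA only, 2272 did not pass the test of the difference, and of 3051 called in polysomal RNA only, 2884 did not. These comparisons share no array, but they share the slides and 1 estimate of the spread per gene, so their calls are not independent. With the slide as a block 7191 genes were called in both, with normexp background correction 3924.

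The interaction compared the polysomal with the total RNA response and so measured the change of polysomal loading with CPX, relative to other genes. Against the spike-in probes described at the end, the array level moved with CPX by −0.22 in total and 0.40 in polysomal RNA (exact permutation p = 0.3 in each). Scaling to these probes would raise every loading change by the difference of these values, so losses below hold only relative to other genes. Ribosomal protein genes lost loading relative to other genes, with a median of −0.73 over 81 genes and 17 of them called lower (camera adjusted p = 2.27e-32; adjusted p = 0.336 with an estimated correlation), and 77 were lower adjusted over the list alone. Targets of p53 did so too, with a median of −0.65 and 8 of 30 called lower (adjusted p = 8.44e-15; adjusted p = 0.265 with an estimated correlation), or 23 adjusted over the list alone. CDKN1A lost 1.60 on the log2 scale (−1.60 ± 0.187, adjusted p = 0.00964), in that its polysomal rise was smaller than its rise in total RNA. Cholesterol synthesis genes gained loading, with a median of 0.53 and 2 of 25 called higher (adjusted p = 5.08e-11; adjusted p = 0.336 with an estimated correlation), or 11 adjusted over the list alone.

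Ribosomal protein genes with a called loss of loading included RPS15A at −1.20 ± 0.146 and RPS9 at −1.14 ± 0.166. The list median was −1.13, −0.52 and −0.59 on the 3 slides and −0.19 after quantile normalization, where the median of all genes was 0.00 instead of −0.10. Cytosolic ribosomal protein genes in total RNA had a median of 0.21 with 2 of 81 called higher (adjusted p = 0.0144; adjusted p = 0.714 with an estimated correlation), none adjusted over the list alone, and a median of −0.02 with scaling to the array median. Of the p53 targets, TIGAR was at −1.44 ± 0.205 and the ferredoxin reductase gene FDXR at −1.22 ± 0.144. The p53 list median was −0.55, −0.72 and −0.74 on the 3 slides. HIF targets had a median of −0.39 with 4 of 39 called lower (adjusted p = 0.000181; adjusted p = 0.336 with an estimated correlation), 7 adjusted over the list alone. Histones, immediate-early genes and metallothioneins had medians of −0.67, −0.60 and −0.58 with no called member (adjusted p = 7.62e-08, 0.000938 and 4.74e-05; adjusted p = 0.718, 0.336 and 0.336 with an estimated correlation). Within the lists 16, 9 and 7 of their members were lower.

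Genes with higher loading after CPX included NNMT, encoding a nicotinamide methyltransferase, at 2.15 ± 0.28 (adjusted p = 0.011), the chemerin receptor gene CMKLR1 at 2.02 ± 0.288 (adjusted p = 0.0139) and the chromatin factor gene DPF3 at 1.97 ± 0.223 (adjusted p = 0.00964). The mitotic genes HMMR and ASPM were higher by 1.12 ± 0.146 and 1.09 ± 0.145. The G2/M list had a median of 0.13 with 5 of 43 called higher (adjusted p = 5.97e-07; adjusted p = 0.336 with an estimated correlation), 6 adjusted over the list alone. Integrated stress response genes had a median of 0.21 with 3 of 36 called higher (adjusted p = 5.97e-06; adjusted p = 0.336 with an estimated correlation), 6 adjusted over the list alone. DDIT3, 1 of these 3, was at 2.48 ± 0.473 (adjusted p = 0.0328), and its adjusted p was over 0.05, up to 0.085, without any 1 of CPX polysomal replicates 1, 2 and 3, CPX total replicates 1 and 2, vehicle total replicates 1 and 3 and vehicle polysomal replicate 3. Genes with lower loading included MAGEL2, a gene of the imprinted Prader-Willi region, at −2.20 ± 0.271 (adjusted p = 0.00964) and FAM83H at −2.06 ± 0.222 (adjusted p = 0.00964). The fibrillin gene FBN1 and the smooth muscle actin gene ACTA2 were at −1.82 ± 0.233 and −1.70 ± 0.195. FTL and FTH1 were at −1.14 ± 0.419 (adjusted p = 0.195) and −0.99 ± 0.371 (adjusted p = 0.202).

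In all, 116 genes had higher and 277 lower loading, all with the same sign on each slide, and 193 and 512 were called with the slide as a block, 113 and 270 of them shared. Normexp background correction left 2 and 1, no filter on dim probes 38 and 75, scaling to the median 89 lower, quantile normalization gave 209 higher, and leaving out CPX polysomal replicate 3 left 22 higher and 34 lower.

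**Figure D2:**
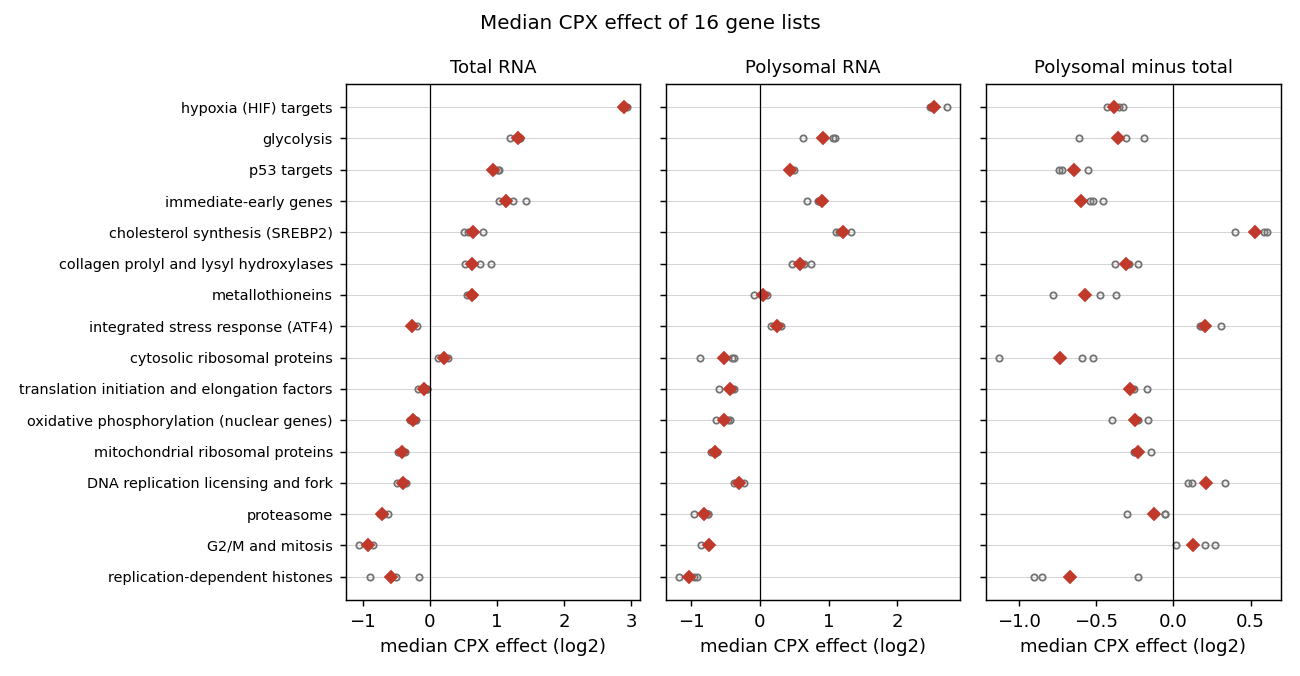
Median log2 change of 16 gene lists with CPX in total RNA, in polysomal RNA and for polysomal loading, with diamonds for the median over the fit and open circles for the 3 slides. HIF targets lie highest with medians of 2.90 and 2.54, and ribosomal protein genes lie at −0.53 in polysomal RNA and 0.21 in total RNA, the latter at −0.02 with scaling to the median.

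**Figure D3:**
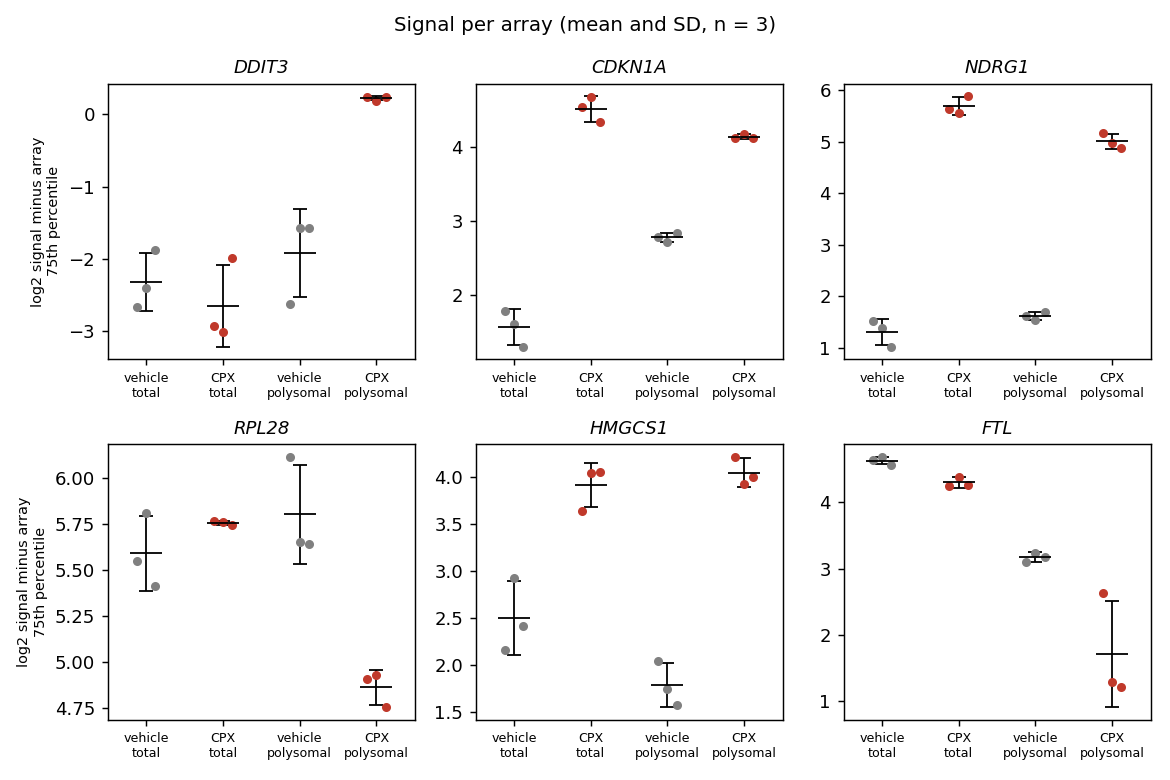
Normalized log2 intensity relative to the 75th percentile of the array for DDIT3, CDKN1A, NDRG1, RPL28, HMGCS1 and FTL in the 4 groups, with a point per array (n = 3) and the group mean and SD. DDIT3 differs between the CPX groups by 2.87 and between the vehicle groups by 0.39, whereas CDKN1A rises from vehicle to CPX by 2.96 in total and by 1.36 in polysomal RNA.

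Polysomal against total RNA in vehicle cells described the polysomal pool at baseline, extraction included. Genes lower in polysomal RNA included IQGAP1, encoding a scaffold of the actin cortex, at −2.93 ± 0.109 (adjusted p = 8.24e-07), the spectrin gene SPTBN1 at −2.42 ± 0.172, the filamin gene FLNA at −2.27 ± 0.316, and the dynein heavy chain gene DYNC1H1 at −2.33 ± 0.131. Histone genes were higher in polysomal RNA, 37 of 50 with none lower and a median of 0.76 (adjusted p = 3.64e-13; adjusted p = 0.579 with an estimated correlation), with H4C8 at 1.39 ± 0.244. The ferritin genes FTL and FTH1 were at −1.46 ± 0.296 and −1.16 ± 0.263. Mitochondrial ribosomal proteins were higher in 41 of 74 cases (median 0.39, adjusted p = 1.24e-10; adjusted p = 0.599 with an estimated correlation).

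Mitotic genes were lower in vehicle polysomes in 22 of 43 cases and higher in 1 (median −0.42, adjusted p = 1.24e-10; adjusted p = 0.364 with an estimated correlation), with the topoisomerase gene TOP2A at −1.73 ± 0.213 and MKI67 at −1.46 ± 0.114. The exon junction gene MAGOH was higher by 2.04 ± 0.143, and the noncoding RNA gene MEG3 by 2.43 ± 0.511. Cytosolic ribosomal protein genes were not called as a list, with a median of 0.00, 1 member higher and 2 lower (adjusted p = 0.358). With p adjusted within each list, 44 histones and 51 mitochondrial ribosomal proteins were higher and 23 mitotic genes lower. In all 2595 genes were higher and 1861 lower, 2985 and 2064 with the slide as a block, and 99.7% of called genes had the same sign on each slide. The counts were 1509 and 1226 without vehicle total replicate 1, and 1557 were higher without vehicle polysomal replicate 3. Limiting the fit to the 6 arrays of this contrast left 983 and 1051, with the block 116 and 280, normexp background correction left 1058 and 1189, and array weights gave 4518 and 2999.

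The same contrast in CPX cells showed ribosomal protein genes low in polysomal RNA, 76 of 81 lower and none higher, with a median of −0.75 (adjusted p = 4.67e-23; adjusted p = 0.539 with an estimated correlation). RPS12 was at −1.34 ± 0.267. FTL and FTH1 were at −2.59 ± 0.296 (adjusted p = 0.000241) and −2.15 ± 0.263 (adjusted p = 0.000321). Metallothioneins were lower in 11 of 11 cases (median −1.02, adjusted p = 8.46e-07; adjusted p = 0.539 with an estimated correlation), with MT2A at −1.43 ± 0.165. Cholesterol synthesis genes were higher in 11 of 25 cases (median 0.46, adjusted p = 0.0011; adjusted p = 0.661 with an estimated correlation), and p53 targets were lower in 17 of 30 cases and higher in 2 (median −0.42, adjusted p = 0.000176; adjusted p = 0.539 with an estimated correlation). Adjusted over the list alone, 80 ribosomal protein genes, 11 metallothioneins and 18 p53 targets were lower, and 12 cholesterol synthesis genes were higher.

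Single genes higher in CPX polysomes included NNMT by 2.90 ± 0.198, DDIT3 by 2.87 ± 0.335 and CMKLR1 by 2.69 ± 0.203, and the receptor kinase gene EPHA2 was at −2.69 ± 0.351. In all 3369 genes were higher and 3729 lower in CPX polysomal than CPX total RNA, 3673 and 4376 with the slide as a block, with 99.7% of called genes of the same sign on each slide. With normexp background correction 1531 were higher and 2368 lower.

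On the hg19 coordinates of the files, the probe of ADM lies on chromosome 11 from 10328780 to 10328839, that of BHLHE40 on chromosome 3 from 5026260 to 5026319 and that of CDC20 on chromosome 1 from 43826537 to 43826596. The TFRC probe lies on chromosome 3 from 195776593 to 195776652, the CDKN1A probe on chromosome 6 from 36654706 to 36654765 and the GDF15 probe on chromosome 19 from 18499890 to 18499949. The FTL probe lies on chromosome 19 from 49469856 to 49469915, the NDRG1 probe on chromosome 8 from 134249719 to 134249778 and the RPL28 probe on chromosome 19 from 55899332 to 55899391. The IQGAP1 probe lies on chromosome 15 from 91044094 to 91044153, the HMGCS1 probe on chromosome 5 from 43290117 to 43290176, the NNMT probe on chromosome 11 from 114183072 to 114183131 and the MAGEL2 probe on chromosome 15 from 23889022 to 23889081. The DDIT3 probe is given on chromosome 12 from 57911200 to 57911526. Probes were designed against transcripts, and with no annotation of hg19 in the reference table their place within exons or untranslated regions is not given.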

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

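The comparison with short transcripts, the test of other mRNAs with a terminal oligopyrimidine tract and the brightness-matched test after quantile normalization were chosen after the result was seen; the other tests were set before. All results given in this part stand out because the CPX response differed between polysomal and total RNA by the interaction test.

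Ribosomal protein genes had a median loading change of −0.73 with CPX, −1.13, −0.52 and −0.59 on the 3 slides. For compression of bright signals, 0% of 10000 lists matched on mean signal reached as low a median (lowest −0.53). This met the bound set beforehand against compression as the whole source. The matched genes were the nearest in rank outside the list, so for the brightest members they can be dimmer. How close the match was in signal was not checked, so the test does not decide on compression. At least a part stays open, as the matched median was −0.36 against −0.10 for all genes. These matched lists, like the others in this part, were drawn gene by gene, so their spread leaves out correlation between genes. Array scaling stays open. The median shrank to −0.19 (−0.185) after quantile normalization, which met the bound of −0.2 set beforehand for scaling as the cause. It was −0.18 in the authors' table, but −0.65 with scaling to the median. In the test chosen afterwards, 0% of lists matched on brightness reached the quantile-normalized value (median 0.11, lowest −0.01). No other test spoke against scaling, and this one concerns only the list's distance from genes of like brightness. It has the same unchecked match, so it does not decide on scaling. A shift common to all genes was not excluded by any of these tests. Short transcripts as a class cannot be told apart as a source, because mitochondrial ribosomal protein and oxidative phosphorylation genes together had a median of −0.24 (95% interval over genes −0.27 to −0.22, 148 genes), between the bounds set for either answer. That interval holds no spread between replicates. A candidate explanation, as a hypothesis, is a lower polysome association of mRNAs with a 5' terminal oligopyrimidine tract. The median of 14 other genes of that class was −0.62, reached by 1.96% of matched lists (matched median −0.38). All 14 lay below 0, but so did the median of all genes (−0.10), and EEF2 at −0.02 ± 0.192 lay above that median. Only 2 of the 14 were called lower over all genes tested, and 13 over the list alone. Their median shrank to −0.18 (matched median 0.06, 0.6% as low) after quantile normalization.

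Targets of p53 had a median loading change of −0.65, with 24 of 30 called higher in total and 17 in polysomal RNA. The choice among these array scalings is argued against as the source, as the highest median under quantile normalization and median scaling was −0.56. Both, like the main scaling, set each array to its own signal, so they cannot exclude a shift common to all genes. Against the spike-in probes described at the end, the array level moved with CPX by −0.22 in total and 0.40 in polysomal RNA. Scaling to these probes would raise every gene's loading change alike. The value for p53 targets therefore holds only relative to other genes. A smaller polysomal change of every induced gene is argued against as the whole source, since 0.03% of 10000 lists matched on the change in total RNA reached as low a median (lowest −0.78). A part stays open, as the matched median was −0.26. These lists too were drawn without correlation between genes, and camera with an estimated correlation did not call the p53 list. A biological effect of CPX on the polysome association of these mRNAs was not tested further and stays open.

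The interaction called 116 genes with higher and 277 with lower loading. Of 100 regroupings of the 12 arrays, 1, the real one, gave as many calls: 393 against 1 in the highest other. The other regroupings mixed the groups and left the slides aside. A real interaction stayed in the values, so it widened their spread and lowered their counts. They are thus no measure of false calls, and chance as the source of a part of the calls is not excluded. A difference in RNA quality between vehicle and CPX polysomal samples was not tested against the loading changes and stays open for them. The probe nearer the 5' end differed from the one nearer the 3' end by −0.08 in vehicle and −0.20 in CPX cells in polysomal minus total RNA, and rho between probe position and loading change was 0.233.

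Further lists with a loading change were HIF targets at −0.39 (−0.385), glycolysis at −0.36, oxidative phosphorylation at −0.25, mitochondrial ribosomal proteins at −0.23, translation factors at −0.28, replication-dependent histones at −0.67, immediate-early genes at −0.60, metallothioneins at −0.58, mesenchymal or Schwann-type markers at −0.43, and housekeeping genes at −0.31. Lists with a higher value were DNA replication at 0.21, homologous recombination and crosslink repair at 0.25, G2/M and mitosis at 0.13, integrated stress response at 0.21, cholesterol synthesis at 0.53 and C2H2 zinc finger genes at 0.012, against −0.10 for all genes. None of the lists held with an estimated correlation. Quantile normalization ended the calls of glycolysis, oxidative phosphorylation, mitochondrial ribosomal proteins, translation factors and zinc finger genes and turned the median of housekeeping genes to 0.11. The authors' table turned those of housekeeping genes to 0.12 and of oxidative phosphorylation to 0.01 (0.005). The replicate block ended the call of the housekeeping genes (adjusted p 0.0479 to 0.0766).

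Single genes with higher loading were DDIT3 (2.48), NNMT (2.15), CMKLR1 (2.02), ELOVL3 (2.00), PLA2G3 (1.99), DPF3 (1.97), SSX4B (1.74) and ARHGAP9 (1.64). Those with lower loading were MAGEL2 (−2.20), DMBX1 (−2.11), FAM83H (−2.06), CSPG4 (−1.83), FBN1 (−1.82), ACTA2 (−1.70), TLL2 (−1.68), P3H2 (−1.61), CDKN1A (−1.60), EGLN3 (−1.22), NDRG1 (−0.996) and BNIP3 (−0.69). Of these 20 genes, 9 kept their call whichever array was left out (NNMT, CMKLR1, DPF3, MAGEL2, FAM83H, FBN1, ACTA2, TLL2 and CDKN1A), but 19 lost it with normexp background correction and 3 with quantile normalization. The highest adjusted p of the others arose without CPX polysomal replicate 3 for ELOVL3 (0.0672), SSX4B (0.0704), ARHGAP9 (0.072), DMBX1 (0.121), CSPG4 (0.074), P3H2 (0.071), EGLN3 (0.114) and NDRG1 (0.108), without CPX total replicate 1 for DDIT3 (0.085) and PLA2G3 (0.105), and without CPX polysomal replicate 2 for BNIP3 (0.0799).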

How the results depend on the processing

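No alternative was chosen after the data were seen. Array weights, arrays, filters and scalings moved the counts as follows, and the cause was not tested unless stated. Normexp background correction gave 2335 genes higher in total RNA, 2505 higher in polysomal RNA, 2 higher and 1 lower for loading, 1058 and 1189 between fractions of vehicle cells, 1531 and 2368 between those of CPX cells and 3924 called in both responses. Scaling to the median gave 6827 lower in total RNA and 89 lower for loading. For loading, quantile normalization gave 209 higher, no filter 38 higher and 75 lower, the authors' values 213 and 183, a trended robust variance 200 and 491, and array weights 606 and 1243. For fractions of vehicle cells, array weights gave 4518 higher and 2999 lower, the arrays of the comparison only 983 and 1051, and these with a replicate block 116 and 280. A threshold of 2-fold gave 2137 and 746 in total RNA, 1944 and 758 in polysomal RNA, 59 and 149 for loading, 328 and 425 in vehicle and 781 and 1037 in CPX fractions and 1831 in both responses, by construction.

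Leaving out each array in turn gave 3879 to 4690 higher and 3495 to 4071 lower in total RNA, 3813 to 4065 and 4453 to 4863 in polysomal RNA, 22 to 113 and 34 to 323 for loading, 1509 to 2289 and 1226 to 1605 for vehicle fractions, 2409 to 3085 and 2715 to 3346 for CPX fractions and 5700 to 6750 called in both. For loading, higher and lower counts were 22 and 34 without CPX polysomal replicate 3, 28 and 39 without CPX total replicate 1, 26 and 54 without CPX polysomal replicate 2, 42 and 83 without CPX total replicate 2, 62 and 90 without vehicle total replicate 3, 55 and 97 without vehicle polysomal replicate 3, 47 and 104 without vehicle total replicate 1, 63 and 174 without CPX polysomal replicate 1 and 69 and 180 without vehicle polysomal replicate 1, and 156 lower without CPX total replicate 3.

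Calls higher made up 52.1% in total and 45.1% in polysomal RNA, but 32% and 32.1% with scaling to the median, which moved the all-gene median by −0.23 and −0.14. For loading they were 29.5%, against 52.6% with quantile normalization, 53.4% with scaling to the median and 53.8% in the authors' table. With normexp the loading share was 66.7%, but of only 2 higher and 1 lower calls. Between vehicle fractions they were 58.2% against 47.1% with normexp, and between CPX fractions 47.5% against 57.9% with scaling to the median. Quantile normalization moved the all-gene median by −0.12 in total RNA and 0.10 for loading, the authors' table by −0.11 and 0.10, and normexp by −0.23 in total RNA, −0.25 between vehicle and −0.13 between CPX fractions.

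Of all genes named by the rule, whether or not printed elsewhere, some calls turned direction. With normexp these were SLC18A1 (−0.06, −0.055), FOSL1 (−0.20) and HBA1 (−0.01, −0.008) in total RNA, SLC18A1 (−0.036) and TUBB2A (−0.037) in polysomal RNA, PXDNL (−0.30), CCL1 (−0.36), PTGS1 (−0.295), CDH9 (−0.37), PSCA (−0.36), HFE (−0.25), EPCAM (−0.016) and DIO2 (−0.20) between vehicle fractions, and TSPYL6 (−0.069) and ZNF826P (−0.035) between CPX fractions. With the mean of a gene's probes they were FBXL5 (0.01, 0.008) and B2M (0.195) in total RNA, SF3B1 (−0.031) in polysomal RNA, MXD3 (−0.01, −0.007) and B2M (−0.038) between vehicle fractions and POLQ (−0.32) between CPX fractions. With quantile normalization and in the authors' table they were EIF4EBP1 in polysomal RNA (0.043 and 0.02), and between CPX fractions MRPL45 (0.022 and 0.01), BNIP3 (0.32 and 0.34) and ODC1 (0.34 and 0.35), and LDHA with quantile normalization (0.02, 0.016). NTRK2 in polysomal RNA turned to −0.15 where all 12 arrays had to lie above background.

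The loading median turned to 0.01 (0.005) for oxidative phosphorylation in the authors' table, and for housekeeping genes to 0.11 with quantile normalization and 0.12 in the authors' table. Of the 26 lists called in total RNA, 7 lost the call with quantile normalization, 7 in the authors' table, 6 with normexp and 2 with the rotation test fry. Of 24 in polysomal RNA the losses were 3, 4, 0 and 0, of 18 in loading 5, 4, 2 and 9 beside those that turned, of 18 between vehicle fractions 2, 2, 10 and 3, and of 16 between CPX fractions 3, 3, 4 and 1. With an estimated correlation 24, 23, 18, 18 and 16 lost it.

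Arrays that share a replicate number share a slide. Deviations from the group means correlated between same-numbered arrays with r of −0.02 to 0.522 (median 0.195, 15 of 18 pairs over 0.1), against a median of −0.114 for others, and 11 of 12 arrays lay closest to an array of their own number, a hint from the data. The replicate block over all 12 arrays gave 193 higher and 512 lower for loading and moved other counts by under 1.5 times. It ended the calls of ER chaperones in total RNA (adjusted p 0.0458 to 0.0552), housekeeping genes in loading (0.0479 to 0.0766), autophagy in vehicle fractions (0.0495 to 0.0687), NRF2 targets (0.0371 to 0.0505) and nucleotide synthesis (0.0441 to 0.0577) in CPX fractions, and began that of histones in CPX fractions (0.0781 to 0.0373). Dim signals limit these data: 10506 probes were not well above background on all 3 arrays of any group.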

Other observations

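The tests of transcript length and of broken RNA were set before their results were seen, and of the comparisons in this part only the spike-in differences within slides were chosen afterwards.

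Further gene lists were tested in total RNA, and those called with the preset correlation were not called with an estimated one. Neuronal differentiation genes were higher in 16 of 36 cases and lower in 7 in total RNA (median 0.44, adjusted p = 0.0357; adjusted p = 0.382 with an estimated correlation), with the tau gene MAPT at 2.44 ± 0.15 and NTRK3 at −0.72 ± 0.154. Adrenergic neuroblastoma identity genes had 6 of 27 higher and 11 lower (median 0.01, adjusted p = 0.464), with GATA2 at −1.05 ± 0.201, and mesenchymal or Schwann-type markers had 6 of 20 higher and 3 lower (median 0.22, adjusted p = 0.386), with FOSL2 at 3.53 ± 0.112. NRF2 targets were lower in 7 of 18 cases and higher in 1 (median −0.32, adjusted p = 0.0139; adjusted p = 0.266 with an estimated correlation), with the quinone reductase gene NQO1 at −1.62 ± 0.123 and the heme oxygenase gene HMOX1 at −0.79 ± 0.191. Genes of iron-sulfur cluster and heme synthesis were lower in 11 of 27 cases and higher in 4 (median −0.22, adjusted p = 0.0254; adjusted p = 0.412 with an estimated correlation). TCA cycle genes were lower in 11 of 20 cases (median −0.50, adjusted p = 0.000363; adjusted p = 0.152 with an estimated correlation), with SUCLG2 at −1.63 ± 0.138 and FH at −1.17 ± 0.0969. Ribosome biogenesis genes were lower in 27 of 51 cases and higher in 2 (median −0.35, adjusted p = 3.59e-05; adjusted p = 0.412 with an estimated correlation), with PPAN at −1.12 ± 0.0969, and spliceosome genes were lower in 19 of 36 (median −0.41, adjusted p = 1.79e-06; adjusted p = 0.266 with an estimated correlation), with SRSF2 at −1.06 ± 0.127.

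Among noncoding RNAs kept in the nucleus, 8 of 9 were higher in total RNA (median 1.02, adjusted p = 0.00364, and adjusted p = 0.266 with an estimated correlation). MEG3 was at 4.55 ± 0.511 and KCNQ1OT1 at 2.07 ± 0.215. In polysomal RNA 5 of 9 were higher (median 0.705). With the slide as a block, 4 were higher and 1 lower in polysomal than in total RNA of vehicle cells (camera adjusted p = 0.359). The polysomal fraction was thus not free of them. C2H2 zinc finger genes were higher in 151 of 454 cases and lower in 44 in total RNA (median 0.23, −0.00 with scaling to the median; adjusted p = 0.00449; adjusted p = 0.438 with an estimated correlation). Lists that were not called in total RNA included G1/S cyclins and inhibitors (4 of 22 higher, 10 lower, adjusted p = 0.0718), the BCL2 family (3 of 16 higher, 1 lower, adjusted p = 0.3), the MYC network (7 of 14 higher, 2 lower, adjusted p = 0.101), Wnt targets (3 of 12 higher, 7 lower, adjusted p = 0.251), interferon response genes (3 of 16 higher, 5 lower, adjusted p = 0.578), autophagy genes (8 of 27 higher, 6 lower, adjusted p = 0.776), heat shock genes (1 of 15 higher, 6 lower, adjusted p = 0.0875) and selenoproteins (1 of 21 higher, 7 lower, adjusted p = 0.0875). The kinase inhibitor genes CDKN1A and CDKN1B moved apart, at 2.96 ± 0.133 and −1.13 ± 0.0904.

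Genes with a probe far along the transcript were more often lower in polysomal than in total RNA of vehicle cells: 22.1% were called lower at a position over 4000 bases against 3.2% under 500 bases, with 8.5% and 23.8% called higher and medians of −0.06 and 0.205. For broken polysomal RNA a bound of −0.1 was set beforehand. In 2856 genes with probes far apart on 1 accession, the probe nearer the 5' end lay −0.08 (−0.076) from the other one in vehicle cells. The 95% interval was −0.095 to −0.06, and the value was −0.03 in the 1403 longest. This argues against breakage as the whole source, but only for the mean of these arrays. The intervals were drawn over genes and hold no spread between replicates. A smaller part stays open, since these intervals lie below 0, and in CPX cells the difference was −0.20 (95% interval −0.218 to −0.184), past that bound. Transcript length, for which the probe's position stood in, cannot be told apart from other sources, since Spearman's rho across 15143 genes was −0.369 on the lowest and −0.123 on the highest of the 3 slides, between the bounds set. With the values averaged over the slides, rho was −0.25 in vehicle and −0.05 in CPX cells, and 0.233 for the loading change. No biological explanation of this pattern was tested, and the separate extraction of polysomal RNA may contribute.

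Other splits of the arrays were counted for each contrast of 3 against 3, where 10 splits exist, too few for a share under 0.1. The real split gave 9146 calls in total RNA (highest other 4), 9839 in polysomal RNA (highest other 0), 4456 between fractions of vehicle cells (highest other 1) and 7098 between fractions of CPX cells (highest other 0), so that 1 of 10 splits gave as many in each case. Every other split put arrays of both real groups on each side. A real difference thus widened its spread and lowered its count, so these counts are no measure of false calls.

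Spike-in probes gave a rough view of signal per labelled RNA. The array's 75th percentile lay −1.34 ± 0.209 (SD) log2 units from the mean of 7 E1A spike-in probes in vehicle total, −1.56 ± 0.18 in CPX total, −1.23 ± 0.436 in vehicle polysomal and −0.83 ± 0.307 in CPX polysomal RNA. Within the 3 slides the change with CPX was −0.33, −0.10 and −0.23 in total and 0.58, 0.22 and 0.40 in polysomal RNA, of 1 sign in each fraction. The exact two-sided permutation p, which leaves the slides aside, was 0.3 in both. With scaling to the spike-in probes every gene's loading change would be higher by the same amount. The loading changes given above are therefore relative to the other genes. Polysomal minus total RNA was 0.73 in CPX cells (exact permutation p = 0.1) and 0.11 in vehicle cells (exact permutation p = 0.8), where 0.1 is the smallest that 3 against 3 arrays allow.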
